A study of Mus musculus with 4 samples.

How the data were processed

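Periosteum, the tissue sheath on the outer surface of bone, was taken from male C57BL/6 wild-type mice at postnatal day 28, per the labels. CD45-positive, Cx3cr1-positive cells were sorted by flow cytometry into ACE-positive and ACE-negative fractions and, in a separate table, into CD74-positive and CD74-negative fractions. Total RNA was extracted with Trizol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. Each of the 4 groups holds 1 library, and the labels do not say how many animals went into it. The submitters' processing notes name HISAT2 and the genome build GRCm38. The gene counter, its strand setting, the annotation release and the authors' statistical test are not given in the sources used here.

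The authors deposited 2 tables, one per sorting marker, and each holds a column of size-factor-normalised signal for each of its libraries, per the file headers. The authors' tables also list a linear fold (the ratio positive over negative), its log2 value, a p-value and an adjusted p-value per gene, per the file headers. The labels of the CD74 samples refer to their table under another name, which sets a control against an abbreviation that the labels do not explain. The columns of the CD74 table were taken as CD74-negative and CD74-positive from the name and header of the deposited table, and Cd74 was 4.74-fold higher in the column taken as positive. The table for ACE lists 14939 genes and that for CD74 lists 14943 genes. Genes with at least 1 read in either library of a table are listed, and nearly all of them are protein coding (99.9% and 99.8% of the identifiers found in GENCODE M21, a GRCm38 annotation). Start and end positions were the same as in that annotation for 99.1% of the matched identifiers in both tables. Coordinates are given as in the deposited tables. There were 0 further columns of per-library values.

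The design had been written for read counts, while the deposited values are counts divided by a size factor. Within each library the values were whole multiples of a smallest step, within a tolerance of 0.001 reads for 100% of values, so the whole reads behind them were recovered and used. The authors set size factors between the libraries of a table, so levels from different tables were scaled separately and were set side by side without a test. Reads on listed genes came to 12561196 in the ACE-negative library, 10944171 in the ACE-positive library, 7020232 in the CD74-negative library and 13282126 in the CD74-positive library. A count of 0 allows up to 3 reads, which is 0.239, 0.274, 0.427 and 0.226 CPM on these totals in the same order.

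Recovered reads were scaled to CPM (reads scaled to a common library size) with TMM effective library sizes from edgeR 4.0.16 in R 4.3.3. The log2 ratio of a gene was computed from CPM + 1, which understates the ratio of genes with few reads. Folds were computed from CPM without the added 1, each with an exact conditional binomial (Clopper-Pearson) 95% interval. Intervals per library are exact Poisson 95% intervals. Reads carry no molecular identifiers, so all intervals and floors cover counting error only. A gene was called higher or lower when its mean was at least 5 CPM, its log2 ratio was at least 1 in size, and the interval of its fold excluded 1. These calls compare 2 libraries, not the conditions behind them. With 1 library per group no residual degrees of freedom remain, so edgeR's quasi-likelihood test and DESeq2's test could not be fitted to the recovered reads, and no p-value, SD or SE between samples was computed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.

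Before the data were examined, 33 gene lists (cell types and pathways) and 2 lists defined by symbol (ribosomal proteins, mitochondrially encoded genes) were fixed. A list was described where at least 3 members had a mean of at least 1 CPM. Its median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to stand apart below percentile 2.5 or above 97.5, as a description of these libraries. A few lists share a gene: Pf4, for example, is in both the LYVE1-positive resident macrophage list and the platelet list. Pdgfb is in both the angiogenic factor list and the osteogenic growth factor list. Where a symbol was listed more than once, the row with the highest mean was used. Genes named in the text follow a rule fixed at the same time. It takes the 4 genes of the sorting markers, the 10 called genes with the largest increase and the 10 with the largest decrease in log2 ratio. From each list it takes the 2 members with the highest mean and the 2 with the largest log2 ratio in size among members with a mean of at least 5 CPM. Of the genes taken by this rule, 1 is left out of the text and not reported here. A few further genes are named as chosen after their values were seen.

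On simulated counts for the genes of the ACE table (14939 genes), 100% of genes changed 3-fold and 100% of those changed 8-fold were called in the right direction, against 0% of those changed 1.5-fold. For the CD74 table (14943 genes) the shares were 98.5%, 100% and 1.49%. Among unchanged simulated genes 0 were called in either table, and 4.50% and 5.00% of random unchanged lists stood apart. The simulation held counting error and no variation between animals or sorts.

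The alternatives tried were pseudocounts of 0.1 and 5, DESeq2 1.42.0 median-of-ratios size factors, plain totals, totals without the 50 most abundant genes and mitochondrial genes, no filter or a minimum of 20 CPM, a 4-fold threshold, a list minimum of 5 CPM, and the correlation without non-macrophage cell type lists. Ratios centred within 20 bins of gene length (as listed in the deposited tables) or of transcript GC content were added after seeing the data. The listed length is not the span from start to end position.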

Results

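Messenger RNA was measured by RNA-seq in CD45-positive, Cx3cr1-positive cells sorted from mouse periosteum at postnatal day 28. The series asks how gene expression differs between subsets of these periosteum-resident macrophages. Cells were parted by surface ACE, the angiotensin-converting enzyme, and, in a separate table, by CD74, the invariant chain of MHC class II. There were 4 groups of 1 library each, with no replicates, so no difference given here has a replicate check. Reads on listed genes ranged from 7020232 in the CD74-negative library to 13282126 in the CD74-positive library. Between 13409 and 14618 genes had at least 1 read in a library. Values are CPM (reads scaled to a common library size), and the intervals in brackets are 95% intervals that cover counting error only.

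The genes of the sorting markers were examined first, since they check the labels. Ace (ENSMUSG00000020681, GRCm38 chromosome 11, 105967945 to 105989964) stood at 11.6 CPM [9.75 to 13.7] in the ACE-negative library and 1215 CPM [1195 to 1235] in the ACE-positive library. Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652) stood at 455 CPM [439 to 472] in the CD74-negative library and 2157 CPM [2133 to 2181] in the CD74-positive library. Each marker was also higher in the positive library of the other sort: Cd74 was 6.64-fold higher [6.47 to 6.81] in the ACE-positive library, and Ace was 3.62-fold higher [3.27 to 4.01] in the CD74-positive library. Cx3cr1, the fractalkine receptor used in the gate, was present in all 4 libraries, from 158 CPM in the CD74-negative to 475 CPM in the ACE-positive library. Ptprc, which encodes CD45, ranged from 831 CPM in the ACE-negative to 1585 CPM in the ACE-positive library. Within the ACE sort, Cx3cr1 was 2.64-fold higher [2.51 to 2.77] and Ptprc 1.91-fold higher [1.86 to 1.95] in the positive library. Within the CD74 sort they were 1.79-fold [1.68 to 1.92] and 1.32-fold [1.28 to 1.36] higher. Only Cx3cr1 in the ACE sort passed the threshold for a call. Centred by gene length, the log2 ratio of Ptprc fell from 0.93 to 0.36 in the ACE sort and from 0.40 to -0.27 in the CD74 sort. That of Cx3cr1 was 1.46 and 0.88 after centring. The direction of Ptprc in the CD74 sort is thus not settled.

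**Figure D1:**
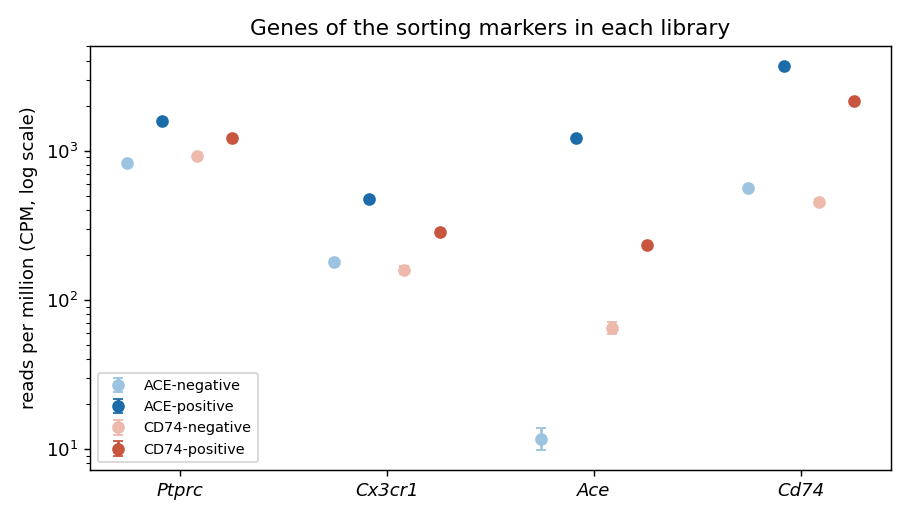
Expression of the genes of the 4 sorting markers (x axis) in CPM on a log scale (y axis), one point per library with exact Poisson 95% intervals that cover counting error only. Ace stands at 11.6 CPM in the ACE-negative and 1215 CPM in the ACE-positive library, and Cd74 at 455 CPM in the CD74-negative and 2157 CPM in the CD74-positive library.

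The ACE-positive library held higher levels of genes of nonclassical, patrolling monocytes, and its MHC class II list and its phagocytic receptor and complement list also stood above random lists. Cd300e, an activating myeloid receptor, was 308-fold higher [132 to 950], from 0.417 CPM to 129 CPM. Adgre4, an adhesion G protein-coupled receptor, was 30.6-fold higher [27.3 to 34.5], and Treml4, a myeloid receptor, was 31.4-fold higher [26.0 to 38.2]. Cd36, a scavenger receptor for lipids, was 22.6-fold higher [18.5 to 27.8], and Fcgr4, an activating Fc receptor, was 21.7-fold higher [18.9 to 25.2]. Lower in the ACE-positive library were Lgals1, which encodes galectin-1 (6.09-fold [5.85 to 6.35]), S100a10 (5.78-fold [5.46 to 6.13]) and Cd7, a lymphoid surface protein (8.88-fold [6.81 to 11.8]).

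The other genes among the 10 largest increases were Lilra5 (241-fold [82.3 to 1173.5], from 3 reads in the ACE-negative library), Dnah12 (110-fold), Slc12a2 (33.8-fold) and Eno3 (24.0-fold), besides Ace itself. The other genes among the 10 largest decreases were Klk8, C1galt1c1, Depdc1a, Upb1, Lmo1, Gzma and Mxd3, between 5.06-fold (C1galt1c1) and 9.65-fold (Klk8) lower.

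Of the 15 measured genes of the nonclassical monocyte list, 12 were higher, 0 lower and 3 neither, with a median log2 ratio of 2.78. Nr4a1, a transcription factor that these monocytes need, was 3.35-fold higher [3.27 to 3.44] and the integrin gene Itgal 3.53-fold higher [3.40 to 3.66]. Nr4a1 is also an immediate early gene, and genes of that kind were higher in the same library, so its ratio alone does not mark these monocytes in either sort. Of 11 classical monocyte genes, 0 were higher and 6 lower, with a median of -1.06. Fn1 was 2.89-fold lower [2.83 to 2.95] and Chil3 2.66-fold lower [2.59 to 2.73], while Plac8 was 1.23-fold lower. Centred by gene length, Chil3 was no longer called (log2 ratio -1.41 before and -0.86 after). In the MHC class II list 4 of 13 genes were higher and 0 lower (median 0.65), among them H2-Aa at 5.83-fold [5.64 to 6.03] and H2-Eb1 at 6.93-fold [6.65 to 7.22].

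Among 20 macrophage core genes, 8 were higher and 1 lower. Mertk, a receptor for apoptotic cells, was 21.4-fold higher [13.8 to 34.9] and the complement gene C1qc 12.2-fold higher [10.9 to 13.7], whereas Lyz2, the most abundant member, was 2.19-fold lower [2.17 to 2.20]. The call of Lyz2 was lost when centred by gene length, which took its log2 ratio from -1.13 to -0.42, and under plain totals. The list of LYVE1-positive resident macrophages had 10 of 14 genes higher and 1 lower (median 1.67). Lyve1 itself was near absent, with 9 reads in the ACE-negative and 7 reads in the ACE-positive library, and is not among the 14 measured genes. Gas6 was 9.29-fold higher [6.98 to 12.6] and Stab1 8.44-fold higher [6.72 to 10.7], while F13a1 was 4.58-fold lower [4.45 to 4.73]. Of 13 phagocytic receptor and complement genes, 7 were higher and 1 lower (median 1.11). Of 15 cholesterol and lipid genes, 5 were higher and 0 lower (median 0.32). The list did not stand apart under the main settings, and did so after centring by gene length (0.37) or GC content (0.46). Apoe, the apolipoprotein that carries cholesterol, was 8.11-fold higher [7.84 to 8.40], and Pparg, a lipid-sensing nuclear receptor, was 24.7-fold higher [18.6 to 33.4].

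Lists of osteogenic, angiogenic, neurotrophic and renin-angiotensin genes also had higher medians in the ACE-positive library. Of 11 osteogenic growth factor genes, 4 were higher and 0 lower (median 1.51), with Igf1 at 5.13-fold [3.97 to 6.69] and Tgfb1 at 1.16-fold [1.11 to 1.21]. Of 14 angiogenic factor genes, 3 were higher and 1 lower (median 0.77), with Cxcl12 at 13.9-fold [12.4 to 15.5] and Pdgfb at 11.7-fold [8.60 to 16.2]. Pdgfb is also among the genes called higher in the osteogenic list. Of 10 neurotrophic and axon guidance genes, 2 were higher and 1 lower (median 0.68), with Nrp2, which encodes a membrane receptor, at 10.1-fold [8.36 to 12.2]. The other gene called higher, Sema4d, lost its call when centred by gene length (log2 ratio 1.02 before and 0.89 after). This last list lost its place apart from random lists with pseudocounts of 0.1 or 5, with a list minimum of 5 CPM and after centring by gene length. Of 7 measured genes of the renin-angiotensin and kinin system, 3 were higher and 0 lower (median 1.52). Agt, which encodes angiotensinogen, was 29.6-fold higher [13.3 to 81.8], from 6 reads in the ACE-negative library. The call of Lnpep was lost when centred by gene length (log2 ratio 0.68), and that of Anpep with a pseudocount of 5. Centred by gene length, the list still stood above random lists (median 1.54).

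Genes of dividing cells were lower in the ACE-positive library. Of 18 cell cycle genes, 15 were lower and 0 higher (median -1.29), with Stmn1 4.09-fold lower [3.84 to 4.35] and Mki67 1.51-fold lower [1.45 to 1.57]. Of 91 ribosomal protein genes, 53 were lower and 1 higher (median -1.06, and -0.60 when centred by gene length, still below random lists), and of 12 mitochondrially encoded genes 5 were lower and 0 higher (median -0.97). Centred by gene length, the mitochondrial list no longer stood apart, with a median of -0.31.

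Markers of other cell types differed between the same libraries. Of 18 fibroblast and periosteal progenitor genes, 11 were higher and 1 lower in the ACE-positive library and the list stood above random lists, with Col1a1, a collagen of bone and fibroblasts, at 3.47-fold [3.36 to 3.58]. Of 11 osteoblast and osteocyte genes, 4 were higher and 0 lower (median 1.20), and Bglap2 was 2.53-fold higher [2.12 to 3.02]. The endothelial, osteoclast, mural, erythroid and B cell lists also stood above random lists, with medians of 1.56, 1.52, 2.17, 1.34 and 0.80. Called higher in them were 3 of 15, 7 of 14, 1 of 6, 8 of 12 and 4 of 12 genes, with 0 lower in each. Pecam1, the most abundant endothelial member, stood at 1.06-fold [0.943 to 1.19]. In the mural list Abcc9 was 10.6-fold higher [6.22 to 19.4] and Acta2 1.58-fold lower [1.14 to 2.20]. The T and NK cell list stood below random lists at -1.35 (-0.80 when centred by gene length), with Gzma 5.65-fold lower [4.10 to 7.97] and Cd4 4.72-fold higher [3.63 to 6.20]. Neutrophil genes were abundant in both libraries, with S100a9 at 5777 CPM in the ACE-negative and 3392 CPM in the ACE-positive library. Immediate early and dissociation stress genes also stood above random lists (median 0.60), with 4 of 16 higher and 0 lower, among them Fosb at 2.62-fold [2.55 to 2.68] and Hspa1b at 3.15-fold [3.03 to 3.27].

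Over 9656 genes with a mean of at least 5 CPM, 913 were called higher and 832 lower in the ACE-positive library. At least 4-fold differences were found for 225 genes higher and 26 lower. Of 34 described lists, 25 stood apart (20 high, 5 low), where 1.70 would be expected of lists of unrelated genes. Genes of a list can vary together, so 1.70 is not a chance level for these lists. The authors' deposited table gives 22 genes an adjusted p-value under 0.05, all of them higher, among them Ace (3.01e-07), Cd300e (2.16e-07) and Pparg (0.00584) in the authors' deposited table. Calls were 52.3% higher under the scaling used. The share was 67.2% under plain totals, which moved the median log2 ratio of all genes by 0.13, 62.5% under totals without the most abundant genes and 65.2% after centring by gene length.

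**Figure D2:**
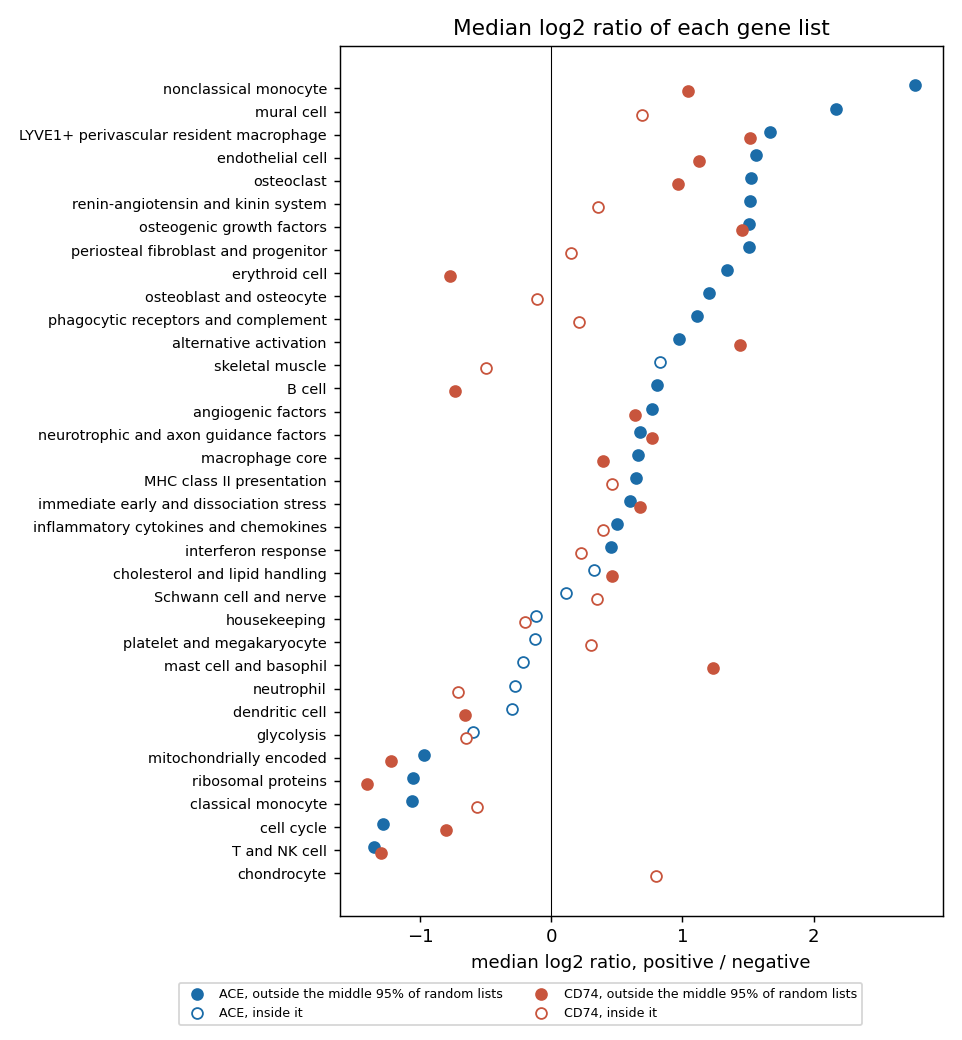
Median log2 ratio of positive over negative library (x axis) for each gene list (y axis), in blue for the ACE sort and red for the CD74 sort. Filled points lie outside the middle 95% of 10000 random lists matched on expression and open points inside it; the nonclassical monocyte list stands at 2.78 in the ACE sort and 1.04 in the CD74 sort.

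The CD74-positive library held higher levels of genes from a list of resident macrophages and of several complement and scavenger receptor genes. The phagocytic receptor and complement list as a whole (5 of 13 higher, median 0.21) and the MHC class II list did not stand apart from random lists under the main settings. Both calls depend on the processing: centred by gene length, both lists stood above random lists, at 0.56 and 0.72, and the MHC class II list also did so under 5 other alternatives. The complement gene C1qa was 16.0-fold higher [13.3 to 19.5], and C1qc stood at 17.0 CPM and 256 CPM. Stab1, a scavenger receptor, was 17.3-fold higher [12.0 to 25.9], Siglec1, a sialic acid receptor of resident macrophages, was 14.0-fold higher [11.6 to 17.2] and Mertk was 21.6-fold higher [11.3 to 47.6]. Itga9 (ENSMUSG00000039115, chromosome 9, 118606690 to 118901003), an integrin gene, was 38.0-fold higher [16.1 to 118]. The gene furthest in the other direction was Lars2 (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666), which encodes the mitochondrial leucyl-tRNA synthetase, at 1422 CPM in the CD74-negative and 30.5 CPM in the CD74-positive library.

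The other genes among the 10 largest increases were Stab2 (47.8-fold [16.2 to 233], from 3 reads in the CD74-negative library), Dab2 (26.3-fold), Kcnj10 (30.2-fold) and C3ar1 (25.1-fold). After Lars2, the largest decreases were in Cd7 (7.16-fold [5.70 to 9.06]), Cd209d, Klrd1, Dctpp1, Gzma, Rpl39, Chchd6, Lmo1 and Lgals1, the last 4.41-fold lower [4.25 to 4.56].

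The list of LYVE1-positive resident macrophages had 8 of 15 genes higher and 0 lower in the CD74-positive library (median 1.51), with Timd4 at 22.7-fold [7.63 to 112] from 3 reads and Selenop at 2.27-fold [2.15 to 2.40]. Lyve1 itself had 14 reads in the CD74-negative and 25 reads in the CD74-positive library (2.13 CPM and 1.76 CPM) and was not called. Of 20 macrophage core genes, 6 were higher and 0 lower (median 0.39). In the MHC class II list 4 of 13 genes were higher and 0 lower, with H2-Aa at 3.85-fold [3.68 to 4.04] and Ciita, the master regulator of these genes, at 6.83-fold [5.27 to 9.01]. Its median of 0.46 lay at the upper limit of random lists and was not counted as apart. Of 15 nonclassical monocyte genes, 8 were higher and 1 lower (median 1.04), with Cd300e at 4.76-fold [3.35 to 6.99] and Nr4a1 at 2.26-fold [2.18 to 2.35]. Of 11 classical monocyte genes, 0 were higher and 0 lower. Of 14 dendritic cell genes, 1 was higher and 4 lower (median -0.66), with Kmo 2.85-fold lower [2.48 to 3.26].

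Of 9 alternative activation genes, 3 were higher and 0 lower (median 1.44), with Socs3 at 2.92-fold [2.68 to 3.18]. Of 7 osteogenic growth factor genes, 3 were higher and 0 lower (median 1.45), with Igf1 at 6.85-fold [4.61 to 10.6] and Pdgfb at 10.3-fold [6.53 to 17.3]. Pdgfb is also among the genes called higher in the angiogenic list. Of 12 angiogenic factor genes, 3 were higher and 1 lower (median 0.64), and Thbs1 was 2.07-fold higher [1.97 to 2.17], a call lost when centred by gene length (log2 ratio 0.90). Of 9 neurotrophic and axon guidance genes, 3 were higher and 0 lower (median 0.77), with Nrp2 at 9.15-fold [7.36 to 11.5]. Of 15 cholesterol and lipid genes, 6 were higher and 0 lower (median 0.47), with Apoe at 4.70-fold [4.48 to 4.92] and Abca1 at 6.23-fold [4.63 to 8.57]. Centred by gene length, the neurotrophic and the cholesterol lists no longer stood apart, with medians of 0.40 and 0.14.

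Ribosomal protein genes were lower in the CD74-positive library: 75 of 90 were lower and 0 higher (median -1.41, and -0.73 when centred by gene length, still below random lists), with Rpl39 4.86-fold lower [4.62 to 5.12]. Of 12 mitochondrially encoded genes 10 were lower and 0 higher (median -1.22), and this list stood apart no longer when centred by gene length (median -0.31). Of 18 cell cycle genes, 4 were lower and 0 higher (median -0.81), with Mcm5 2.72-fold lower [2.58 to 2.86] and Mki67 1.38-fold higher [1.33 to 1.43]. Centred by gene length, the log2 ratio of Mki67 fell from 0.46 to 0.09, while that of Mcm5 stood at -1.32.

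Among markers of other cell types, 5 of 9 mast cell and basophil genes were higher and 0 lower in the CD74-positive library (median 1.24). Prss34 and Mcpt8, proteases of basophils, were 5.90-fold [5.35 to 6.53] and 4.40-fold [3.90 to 4.98] higher. The endothelial list (4 of 15 genes higher, 1 lower) and the osteoclast list (5 of 13 higher, 0 lower) stood above random lists with medians of 1.13 and 0.97. The T and NK cell list stood below them at -1.30 (-0.98 when centred by gene length), with Gzma 5.59-fold lower [4.29 to 7.34]. The erythroid and B cell lists stood below random lists at -0.77 and -0.73, and neither did so when centred by gene length (-0.18 and -0.10). S100a9 stood at 10026 CPM in the CD74-negative and 4179 CPM in the CD74-positive library, a log2 ratio of -1.26 that fell to -0.32 when centred by gene length. Immediate early and dissociation stress genes stood above random lists here too (median 0.67), with 4 of 16 higher and 0 lower, among them Fosb at 3.75-fold [3.63 to 3.88].

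Over 9719 genes with a mean of at least 5 CPM, 882 were called higher and 751 lower in the CD74-positive library. At least 4-fold differences were found for 101 genes higher and 14 lower. Of 35 lists, 19 stood apart (12 high, 7 low), where 1.75 would be expected of lists of unrelated genes. As in the ACE sort, this is not a chance level for these lists. The authors' deposited table gives 1 gene an adjusted p-value under 0.05, Lars2 (8.13e-05 in the authors' deposited table). This value too cannot measure spread between animals or sorts. Of the calls made here, 54.0% were higher under the scaling used. The share was 74.8% under plain totals, with 434 genes lower and a move of 0.18 in the median log2 ratio of all genes, and 66.9% under totals without the most abundant genes.

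Both sorts were then set against each other across genes. H2-Aa, C1qc, Mertk, Stab1 and Apoe were higher in both positive libraries, and Lgals1, Cd7, Gzma and 53 of 90 ribosomal protein genes measured in both tables were lower in both. Across 9533 genes with a mean of at least 5 CPM in both tables, the log2 ratios had a Pearson r of 0.788 and a Spearman rho of 0.805; genes are not independent replicates. Of these genes, 458 were called higher in both, where independent lists would share 77.4. Called lower in both were 452, where independent lists would share 63.7. Ratios moved with gene length in both sorts, as given below, so 77.4 and 63.7 are not chance levels for these genes. Opposite calls were made for 6 genes higher in the ACE-positive and lower in the CD74-positive library, and for 3 genes the other way round. The labels do not say whether both sorts drew on the same animals.

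**Figure D3:**
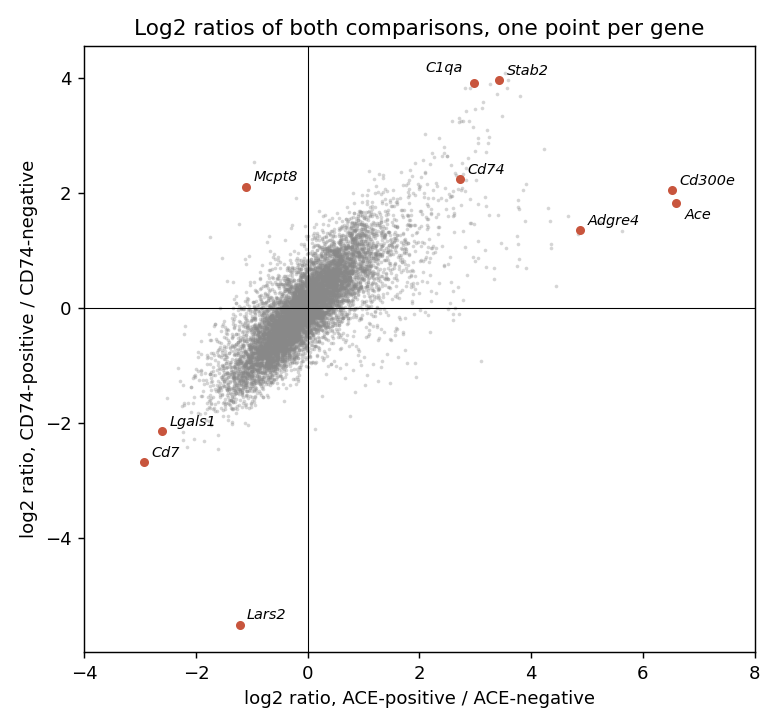
Log2 ratio of ACE-positive over ACE-negative (x axis) against CD74-positive over CD74-negative (y axis), one grey point per gene with a mean of at least 5 CPM in both tables and named genes in red. Most genes lie along the diagonal (Pearson r 0.788 across genes), while Lars2 and Mcpt8 lie away from it.

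The log2 ratios also moved with the listed gene length in both sorts. This length is not the span on the chromosome. The longest among these genes was 123179 bp, while Runx2 runs from 44495987 to 44814797 on chromosome 17. Genes in the shortest decile, with a median length of 1420 bp in the ACE sort, had a median log2 ratio of -0.65 there and -0.82 in the CD74 sort. Those in the longest decile stood at 0.50 and 0.58. Spearman's rho of log2 ratio and length across genes was 0.399 in the ACE sort and 0.505 in the CD74 sort, and 0.388 and 0.495 without ribosomal protein and mitochondrially encoded genes. For GC content rho was 0.0329 and 0.0955.

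**Figure D4:**
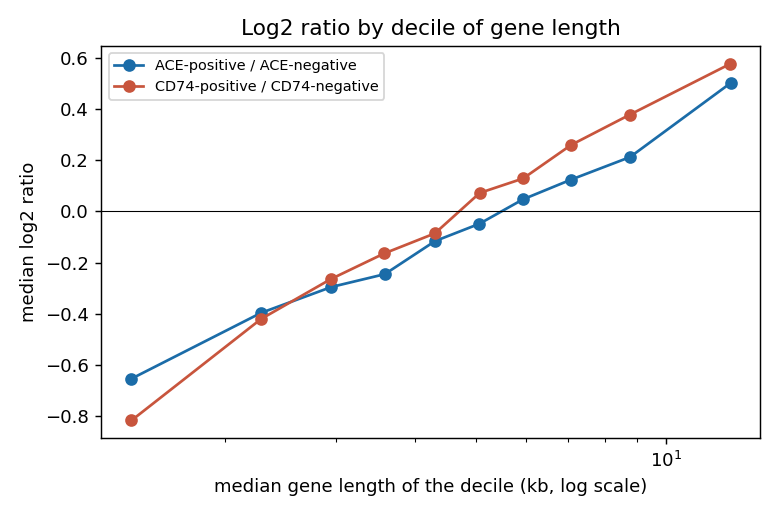
Median log2 ratio of positive over negative library (y axis) by decile of gene length (x axis, median length of the decile in kb on a log scale), in blue for the ACE sort and red for the CD74 sort. The medians run from -0.65 to 0.50 in the ACE sort and from -0.82 to 0.58 in the CD74 sort.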

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

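The differences between sorts given in this part were not tested, since each group holds 1 library; they are listed because the ratio points one way in the ACE sort and the other way in the CD74 sort. The lists are those that stood apart from random lists in at least 1 sort, and the genes are among the named genes called in both sorts. The length and GC adjustments, and the tests of ribosomal RNA reads and of RNA from other cell types, were chosen only after the results were seen.

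More basophil and mast cell genes were called higher in the CD74-positive library (5 of 9, with 0 lower) than in the ACE-positive library (0 of 11, with 3 lower). Not all members went that way: Hdc was 1.53-fold higher [1.40 to 1.69] in the ACE-positive library, under the 2-fold threshold. The list had a median log2 ratio of -0.22 in the ACE sort and 1.24 in the CD74 sort. Mcpt8 stood at -1.10 and 2.11, Cpa3 at -1.23 and 1.47, and Ms4a2, a chain of the high-affinity IgE receptor, at -1.75 and 1.24. Erythroid genes went the other way, with list medians of 1.34 and -0.77 and Hba-a1 at 1.07 and -1.16. The B cell list stood at 0.80 and -0.73, and the osteoblast and osteocyte list at 1.20 and -0.11. The last value was 0.03 under plain totals and 0.10 when length-adjusted, so its direction in the CD74 sort is not settled. Length adjustment also took the CD74 values of the erythroid list to -0.18, of Hba-a1 to -0.21 and of the B cell list to -0.10, and neither list then stood apart. It took the ACE values of Mcpt8 to -0.39 and of Cpa3 to -0.68, under the 2-fold threshold.

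The log2 ratios of both sorts moved together across genes, and ribosomal protein genes were lower in both positive libraries. A trend with gene length or GC content shared by both sorts could give both. After centring within length bins, Pearson r was still 0.757, and after centring within GC bins 0.787, which argues against either trend as the whole source of the correlation. The length-centred median of ribosomal protein genes was -0.60 in the ACE sort and -0.73 in the CD74 sort, against -1.06 and -1.41 before. Centring by the listed length thus removed a part of that difference. It removes no trend inside a bin, so it cannot show whether length accounts for the rest. Whether length inside bins, cell state, sorting or RNA quality lies behind the remainder stays open, because each sort has 1 library per group.

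Lars2 was 46.7-fold lower [42.4 to 51.5] in the CD74-positive library, and the CD74-negative library stood out, with 1422 CPM against 73.8 CPM in the ACE-negative, 31.1 CPM in the ACE-positive and 30.5 CPM in the CD74-positive library. A change of mitochondrial tRNA synthetase genes as a group is argued against: the other 16 had a median log2 ratio of -0.30 (SE of the median 0.13), none below -0.84. Reads of ribosomal RNA assigned to Lars2 could be a source, but 0 of the genes that overlap ribosomal RNA repeats were among the listed genes, so this could not be examined and cannot be told apart from a difference between the cells.

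Fibroblast, osteoblast and erythroid genes were higher in the ACE-positive library, although the cells were gated on CD45 and Cx3cr1; length-centred medians of 1.54, 1.21 and 1.84 argue against a gene length trend. RNA of those cell types in the ACE-positive library stays open. Of the 3 most abundant members of each list, 8 of 9 were higher with a counting interval above 1, but the lists were picked because they were higher and expression by the sorted cells would give the same, so this count decides nothing. The exception was Runx2 at 52.5 CPM in the ACE-negative and 52.3 CPM in the ACE-positive library. RNA of other cells cannot be told apart from expression by the sorted cells, since bulk RNA does not show which cell a read came from.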

How the results depend on the processing

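Alternatives per gene (both pseudocounts, median-of-ratios factors, totals and length adjustment) were run on 184 genes, those taken by the naming rule in either sort or called in opposite directions. No called gene changed direction, but many moved: values left their counting interval for 133 (ACE) and 135 (CD74) genes when length-adjusted and for 86 and 100 under totals. Of 88 genes called higher and 45 lower in the ACE sort, length adjustment kept 86 and 32, totals 88 and 37, and a pseudocount of 5 kept 82 and 42. Of 61 and 45 in the CD74 sort, these kept 58 and 20, 61 and 36, and 54 and 39. The correlation across genes stayed between 0.757 and 0.823. Adjustments for length and GC content were chosen after seeing the data. The number of genes called higher in the ACE-positive library was 1518 with no filter and 571 with a minimum of 20 CPM. With a 4-fold threshold 225 were higher and 26 lower in the ACE sort, and 101 and 14 in the CD74 sort, by construction. Genes called lower came to 469 (ACE) and 400 (CD74) when length-adjusted. Of the genes called lower without adjustment, 377 of 832 (ACE) and 255 of 751 (CD74) were kept, and of those called higher 722 of 913 and 502 of 882. Genes called lower came to 434 in the CD74 sort under plain totals; totals shift all ratios upwards.

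In the ACE sort the neurotrophic list lost its place apart with a pseudocount of 0.1 (0.69) or 5 (0.40), a minimum of 5 CPM (0.29) and length adjustment (0.53). So did the mitochondrial list under length adjustment (-0.31) and the inflammatory list under GC adjustment (0.51). The basophil list came to stand apart with a minimum of 5 CPM (-0.96), and the cholesterol list with length (0.37) or GC (0.46) adjustment. In the CD74 sort the MHC class II list, at the threshold, stood apart with a pseudocount of 5 (0.42), a minimum of 5 CPM (0.46), median-of-ratios factors (0.47), totals (0.65), and length (0.72) or GC (0.48) adjustment. The mural list did so with a pseudocount of 5 (0.39), the neutrophil list with GC adjustment (-0.77), and the glycolysis list with totals (-0.46), length (-0.58) or GC (-0.67) adjustment. Length adjustment ended the place apart of the B cell (-0.10), erythroid (-0.18), neurotrophic (0.40), cholesterol (0.14) and mitochondrial (-0.31) lists, and gave one to the inflammatory (1.10), interferon (0.75) and phagocytic (0.56) lists. Apart from the 4-fold threshold and totals, the cause was not tested.

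No paired analysis was possible because each group has 1 sample. Not run were the FPKM alternative, as the tables used here hold no such values, and the DESeq2 test, leave-one-out and replicate block, which need replicate columns.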

Other observations

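Interferon response genes were higher in the ACE-positive library for 7 of 15 members and lower for 0, with Rsad2 at 3.15-fold [2.88 to 3.44] and Irf7 at 2.17-fold [2.10 to 2.25]. In the CD74-positive library 4 of 15 were higher and 0 lower, with Cxcl10 at 2.18-fold [1.90 to 2.52]. Inflammatory cytokine genes were higher for 3 of 14 in the ACE sort (median 0.50) and for 0 of 13 in the CD74 sort (median 0.39). Il1b was 1.83-fold higher [1.76 to 1.90] in the ACE-positive library and 1.11-fold lower [1.06 to 1.16] in the CD74-positive library, where its log2 ratio was 0.04 under plain totals. Of 9 alternative activation genes 3 were higher in the ACE sort (median 0.97), with Tgm2 at 12.2-fold [9.58 to 15.6]. Glycolysis genes had medians of -0.60 and -0.65. Ldha was 2.16-fold lower [2.07 to 2.25] and Hk2 2.54-fold higher [2.26 to 2.86] in the CD74-positive library. The call of Ldha was lost under plain totals and under length adjustment (log2 ratio -0.91).

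Of 14 dendritic cell genes 3 were higher and 4 lower in the ACE-positive library, with Itgax at 3.61-fold higher [3.27 to 4.00] and Irf8 2.31-fold lower [2.22 to 2.41]. Neutrophil genes had medians of -0.27 (0.08 when length-adjusted) and -0.71, with Prtn3, a granule protease, 3.33-fold lower [3.15 to 3.52] in the ACE-positive library. In the CD74 sort the fibroblast list had 1 of 18 higher and a median of 0.15 (-0.13 when length-adjusted), and the renin-angiotensin list 1 of 8 higher and a median of 0.36. Medians of the platelet list were -0.12 and 0.30, of the Schwann cell list 0.11 and 0.35, of the skeletal muscle list 0.83 and -0.50, and of housekeeping genes -0.12 and -0.20, in the ACE and the CD74 sort. None of these 4 lists stood apart in either sort. The housekeeping median of the ACE sort was 0.01 under plain totals; length adjustment took the platelet median of the ACE sort to 0.21 and the skeletal muscle median of the CD74 sort to 0.07. The chondrocyte list had a median of 0.80 in the CD74 sort and too few measured members (2) in the ACE sort, and the mural cell list a median of 0.70 in the CD74 sort.

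The 6 genes called higher in the ACE-positive and lower in the CD74-positive library included Hba-a1, Aqp1, Cldn13, Rhd and Car1, and the 3 genes with the opposite pair of calls were Mcpt8, Ms4a2 and Cpa3. Aqp1, Cldn13, Rhd and Car1 were named after their values were seen. Length adjustment took their CD74 log2 ratios to values between -0.72 (Aqp1) and -0.24 (Car1), under the 2-fold threshold. Car1, a carbonic anhydrase of red cells, stood at 10.2 CPM and 41.9 CPM in the ACE-negative and ACE-positive libraries, and at 52.1 CPM and 22.4 CPM in the CD74-negative and CD74-positive libraries.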
